A study of Tegula funebralis with 16 samples.

How the data were processed

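Whole animals were frozen and ground, RNA was extracted from each individual, and libraries were sequenced as 100-base paired reads, per the labels' protocols. The deposited table holds 1 column per library, and the submitters' processing notes name CASAVA and DESeq without versions; the assembler, mapper and filters are not given in the sources used here. The deposited values are a signal unit, read counts divided by a size factor per library: 100% of values were whole multiples of the column's smallest step within 0.01 read, and median-of-ratios factors recomputed from the recovered reads equalled the deposited ones. Recovered reads per library ran from 17594009 to 26103215, and intervals on shares of reads are Wilson 95% intervals that cover counting error only. No genome was used here, so contigs have no coordinates, and 6622 of 15903 contigs carry no gene name. Identifiers begin with SR, the letters that sample titles use for Slide Ranch.

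From these values, log2(value + 1) was fitted in limma 3.58.1 (R 4.3.3) with a variance trend, 1 mean per site and treatment (8 groups of 2) and all 16 libraries sharing the spread; contigs with a mean under 10 were left out. Fold changes are on the log2(value + 1) scale, which understates changes of low contigs. Contrasts averaged the sites, p-values were adjusted by Benjamini-Hochberg, and 0.05 was the threshold. For 23 gene lists set by name patterns before the data were examined, 22 had tested members (the mitochondrial chaperone pattern matched none, as it missed the spelling of the HSP60 contig), and camera was run with a correlation of 0.01 and, as an alternative, an estimated one. Named contigs were, for heat over the 4 sites, heat in each region, the interaction and the control baseline, up to 6 of the largest rises and 6 of the largest falls with adjusted p under 0.05, a mean of at least 50, the same direction at every site concerned and an informative name, plus up to 3 contigs per list with the smallest p under heat; contig SR_contig_83 and the few others marked so where they are named were chosen after their values were seen. Count models, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0, were run on the recovered reads as alternatives.

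Other alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, TMM scaling, recomputed median-of-ratios scaling (which moves nothing, as the values already have it), a minimum log2 change of 1, robust shrinkage, only the libraries compared, a replicate block, site as a random effect, and leaving out each library or site. Added after the data were examined were fits without the 4 libraries that stand apart, fits with a term for them, site as a random effect without them, gene lists between controls also without La Jolla control 2, regional slopes over a fixed set of contigs, and further control splits in the baseline comparison, of which 12 settings were run in all, 5 of them planned. Where a fit leaves a group with 1 library, that library is assumed to vary like the others. The steps were tested on simulated reads with the real means and spread. Reads were drawn independently for each library, and changed contigs were taken from those with a mean of at least 50. For heat averaged over sites, over 14444 contigs, limma recovered 23.5% of 200 contigs changed 1.5-fold, 71.5% at 2-fold and 98.0% at 4-fold. Of all calls, 3.30% were false. To look for a library deposited more than once, the counts of a group's 2 libraries were compared, where such a pair would give a chi-square per degree of freedom near or under 1. The values lay between 21.2 and 1955, and the check bears on nothing else. Figures were drawn with matplotlib 3.10.9.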

Results

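Transcript abundance was measured by RNA sequencing of whole animals of the intertidal snail Chlorostoma (Tegula) funebralis from 4 sites in California. Slide Ranch and Pigeon Point are northern sites, and Aliso Beach and La Jolla are southern sites. At each site, 2 libraries came from control animals kept in air at 15 °C for 5.5 hours and 2 from animals whose air temperature was raised from 15 °C in steps of 3 °C to 34 °C within the same 5.5 hours, which gave 8 groups of 2 and 16 libraries in all. The table held 15903 assembled contigs, of which 14444 had a mean normalised read count of at least 10 and were tested. The reads recovered per library ran from 17594009 to 26103215. A contig is an assembled transcript or part of 1, so several contigs with the same name may belong to 1 gene or to close copies, and reads could be shared between them. The labels do not say how many animals each library holds, so p-values measure the spread between these libraries.

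The first libraries of Pigeon Point and La Jolla, control and heat, stood apart from the other 12. Contig SR_contig_83, named senescence-associated protein in the table, took 16.6%, 17.3%, 17.1% and 39.2% of their reads, against 1.58% to 6.80% in the others, with Wilson 95% intervals such as 39.20% to 39.23% for the last. The first principal component, with 41.9% of the variance, separated these 4 libraries from the rest. Ribosomal protein contigs had a median log2 difference of 0.96 and contigs of mitochondrial respiration one of 0.86 in them, and of ovary and egg markers 0.45, while muscle markers had -0.32 and testis and sperm markers -0.29. Each region and each treatment held 2 of the 4, so counts of calls are given for the other 12 libraries too, an alternative chosen after the data were examined.

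**Figure D1:**
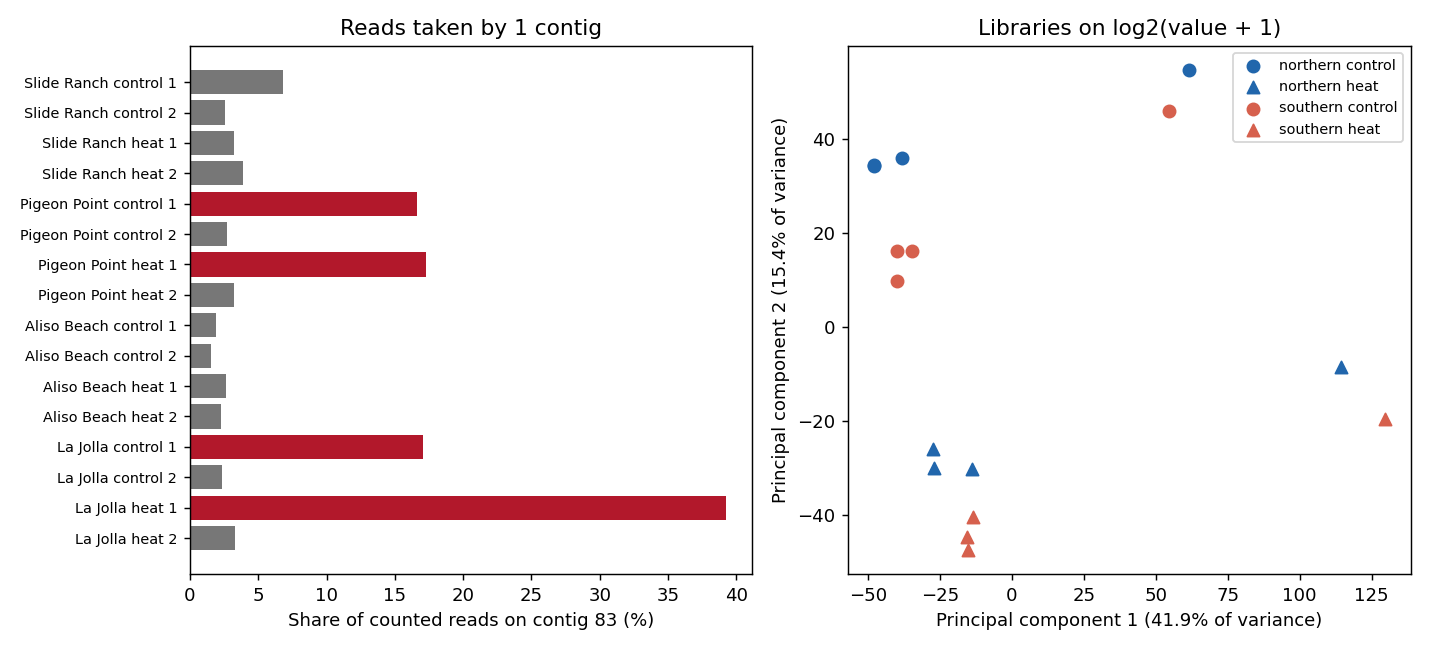
Left, bars give the share of counted reads on contig SR_contig_83 in each of the 16 libraries (%), with the 4 libraries that stand apart in red. Right, each point is a library on the first 2 principal components of log2(value + 1), with 41.9% and 15.4% of the variance, where the same 4 libraries lie at the right.

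The 4 largest rises under heat among the named contigs were those of heat shock proteins, chaperones that refold or hold damaged proteins. HSP70 contig SR_contig_18771_C3.1 rose from 369 ± 289.8 to 408957 ± 89713 normalised counts (SD, n = 8 each), a log2 fold change of 10.44 ± 0.29 (SE). The small heat shock protein 26 contig SR_contig_5896_C3.1 rose from 139 ± 134 to 59780.3 ± 29801 (log2 fold change 9.14 ± 0.34), and HSP90 contig SR_contig_806_C3.1 from 7161 ± 1311 to 91932 ± 20981 (log2 fold change 3.67 ± 0.13). Of the HSP70 list, 6 of 8 contigs rose, as did the single HSP90 contig, 3 of 3 small heat shock proteins and 8 of 18 HSP40 and co-chaperone contigs, and none of them fell. Adjusted over the list alone, 7 HSP70 and 10 HSP40 and co-chaperone contigs rose, and in the 12 other libraries 7 and 10. Among the partners of HSP70, DNAJB1 (SR_contig_17338) had a log2 fold change of 7.44 ± 0.14 (SE) and the BAG3-like regulator (SR_contig_31772) one of 7.24 ± 0.10. Across the averaged contrast, 613 contigs changed in limma at a Benjamini-Hochberg adjusted p under 0.05, 301 higher and 312 lower, and 2712 in the 12 other libraries, 1525 higher and 1187 lower. Of the 613, 609 were also called with the same sign in those 12. With 1 library left out, the count was 403 without Slide Ranch control 2, 404 without Aliso Beach control 2 and 1097 without La Jolla heat 2.

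**Figure D2:**
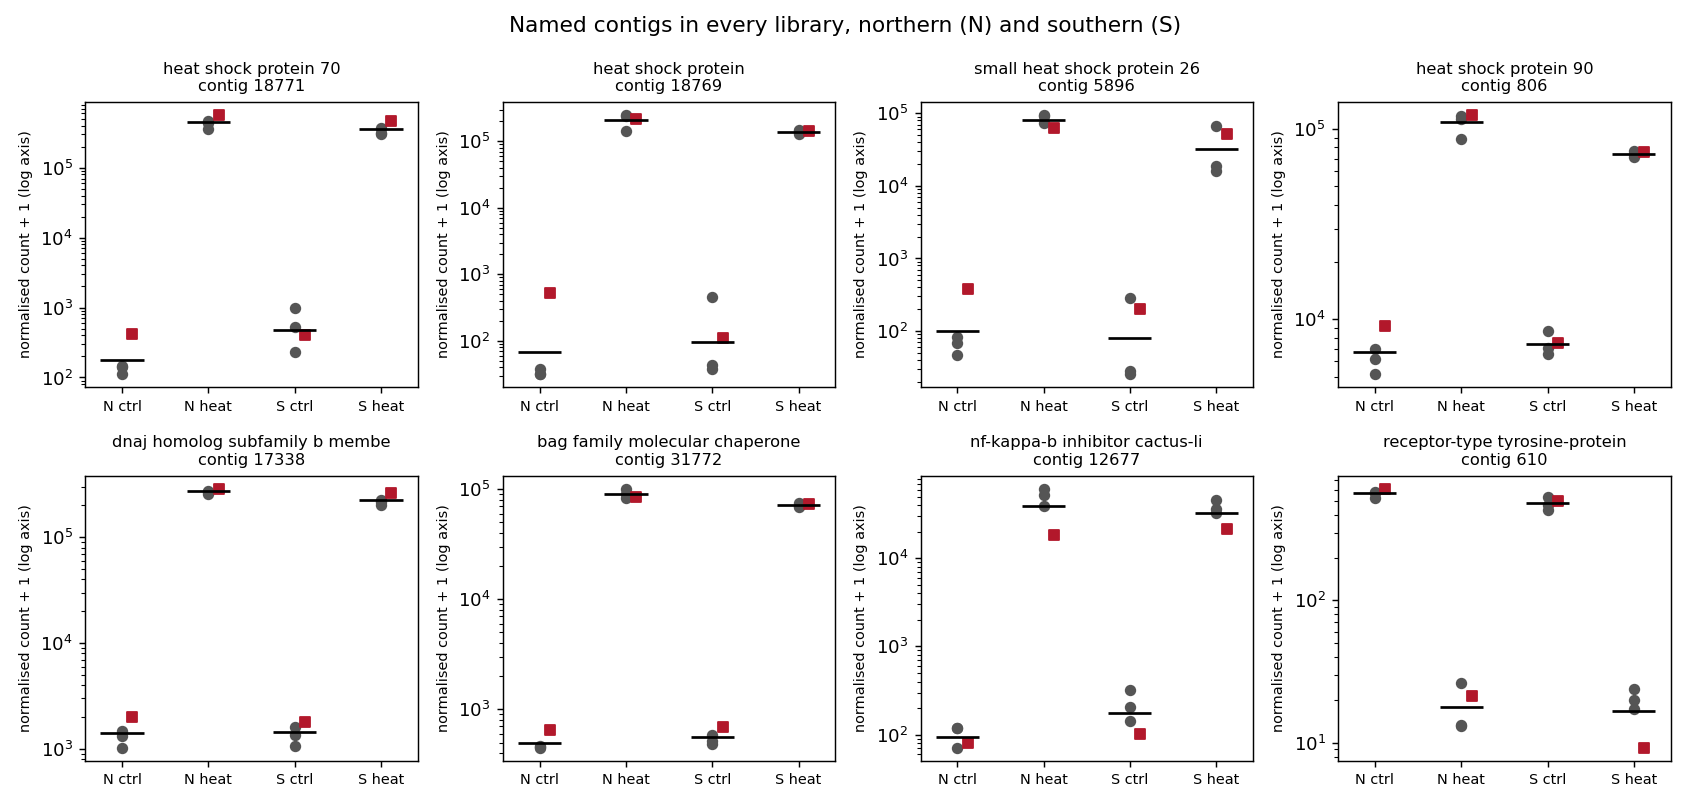
Normalised count + 1 (log axis) of 8 named contigs in each library, by region and treatment, with a line at the mean of log2(value + 1) of 4 libraries and red squares for the 4 libraries that stand apart. HSP70 contig SR_contig_18771_C3.1 lies between 111 and 979 in controls and between 307406 and 570418 under heat.

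Both contigs named for the HSP70 of the endoplasmic reticulum rose. A BiP-like contig (SR_contig_18099_C3.1), which the name pattern of that organelle's list leaves out, went from 1.61 ± 2.05 to 576 ± 366 (SD, n = 8 each), so its log2 fold change of 7.88 depends on the pseudocount. The mitochondrial chaperone HSP60 (SR_contig_13515_C3.1), which no list holds and which was chosen after its values were seen, rose with a log2 fold change of 1.52 ± 0.21 (SE) and an adjusted p of 0.00114 in limma. GRP78 (SR_contig_7836), of the endoplasmic reticulum unfolded protein response list, rose with a log2 fold change of 2.12 ± 0.33 (SE) and an adjusted p of 0.00296 in limma. It was the only one of its 8 members to pass over 16 libraries (4 rose in the 12). The list's camera call (adjusted p = 0.011) was lost with an estimated correlation (adjusted p = 0.478). In the ubiquitin and proteasome list 8 of 180 rose and 5 fell, against 28 and 12 in the 12, and sequestosome 1-like (SR_contig_7824), an adaptor that carries tagged proteins to autophagy, rose from 1755 ± 974 to 17643 ± 6426 (SD, n = 8 each). Among 40 antioxidant enzymes, 2 rose, a glutathione S-transferase omega (SR_contig_1795, log2 fold change 1.02) and thioredoxin reductase 3 (SR_contig_617_C3.1, 1.52). The first lost its call without Aliso Beach control 1 or Aliso Beach heat 2, and the second without any library except Pigeon Point control 1, Pigeon Point heat 2, La Jolla control 1, La Jolla heat 1 and La Jolla heat 2. In the 12 libraries 9 rose and 1 fell. The list's adjusted p was 0.0122, or an adjusted p = 0.478 with an estimated correlation. In the 4 libraries that stand apart 6 of the endoplasmic reticulum and 22 of the antioxidant contigs were higher, with list medians of 0.74 and 0.54 (log2).

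Regulators of cell death and of transcription moved in both directions. Of 87 apoptosis and survival contigs, 10 rose and 9 fell, against 12 and 14 in the 12 libraries. The inhibitor of apoptosis BIRC3-like (SR_contig_6960_C3.1) rose from 428 ± 62.6 to 46368 ± 7889 (SD, n = 8 each), a log2 fold change of 6.75, and a second baculoviral IAP repeat contig (SR_contig_4364) had a log2 fold change of 3.63, while fas ligand (SR_contig_3972_C3.1), a trigger of cell death, fell by 2.15 on the log2 scale. Members also went the other way, chosen here after their values were seen: an inhibitor of apoptosis contig (SR_contig_5700) fell by 2.51 and a contig like the death promoter BAX (SR_contig_15738) rose by 1.90. Of 18 contigs in the list of stress transcription factors, which by its name pattern also holds inhibitors of NF-kappa-B, 4 rose and 2 fell, against 5 and 2 in the 12. A cactus-like inhibitor of NF-kappa-B (SR_contig_12677_C3.1) rose with a log2 fold change of 8.13 ± 0.26 (SE), another (SR_contig_17890_C3.1) with 6.01, and AP-1 (SR_contig_7953) with 1.78, whereas KLF2-like (SR_contig_2247) fell by 2.38. That list's camera call (adjusted p = 0.0108) was lost with an estimated correlation (adjusted p = 0.0714). The deepest fall among named contigs was that of receptor-type tyrosine phosphatase T (SR_contig_610), from 526 ± 59.8 to 17.1 ± 5.88, followed by 2 EGF-like domain contigs with log2 fold changes of -3.70 and -3.64. Timeless (SR_contig_21934), a clock and replication protein, fell by 2.22.

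Metabolic and tissue lists gave few calls over all 16 libraries and more in the 12. Of 79 ribosomal protein contigs 3 rose and 1 fell, against 41 and 1 in the 12 libraries, with a median log2 fold change of 0.38. Of 65 mitochondrial respiration contigs 0 passed in limma (6 at an unadjusted p under 0.05, 0 called by edgeR and 2 by DESeq2), against 28 in the 12. Of 36 ovary and egg contigs 3 rose, 17 adjusted over the list alone and 27 in the 12, among them a vitelline envelope contig (SR_contig_1028_C3.2, log2 fold change 0.67). The camera adjusted p of these 3 lists was 3.8e-08, 2.4e-06 and 1.7e-09, and with an estimated correlation the adjusted p was 0.478, 0.483 and 0.136. The same 3 lists were higher in the 4 libraries that stand apart, as given above. With an estimated correlation the calls of HSP70, small heat shock proteins and HSP40 with co-chaperones held (adjusted p = 0.0206, 0.0206 and 0.0265) over 16 libraries, and no other list's did. In the 12 libraries their adjusted p with an estimated correlation was 0.0996, 0.0475 and 0.0475, so that of HSP70 no longer passed.

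The remaining lists held few changes over all 16 libraries and more in the 12. Over all 14444 tested contigs limma called 613, and 2712 in the 12. Of 113 immune and pattern recognition contigs 1 rose and 4 fell, against 16 and 10 in the 12 libraries. Of 15 glycolysis and gluconeogenesis contigs 1 rose and 1 fell, against 6 and 1 there. Of 72 cytoskeleton contigs 1 rose, and in the 12 libraries 4 rose and 2 fell. No contig passed in limma among 27 of ion and acid-base transport, 34 muscle, 82 digestive gland, 61 testis and sperm, 67 mantle and shell, 14 blood and 5 ingested or symbiotic organism markers, in that order. At an unadjusted p under 0.05 there were 3, 8, 15, 8, 10, 2 and 0, edgeR called 0, 0, 0, 0, 0, 0 and 0, and DESeq2 called 0, 5, 2, 2, 4, 0 and 0. In the 12 libraries limma called 3, 6, 21, 8, 18, 2 and 1. The digestive gland and testis lists had camera calls (adjusted p = 0.0126 with a median log2 fold change of 0.22, and 0.0473 with -0.13), which were lost with an estimated correlation (adjusted p = 0.478 and 0.593). Digestive gland, glycolysis, immune and mantle contigs also had higher list medians in the 4 libraries that stand apart, of 0.43, 0.34, 0.17 and 0.47 (log2).

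**Figure D3:**
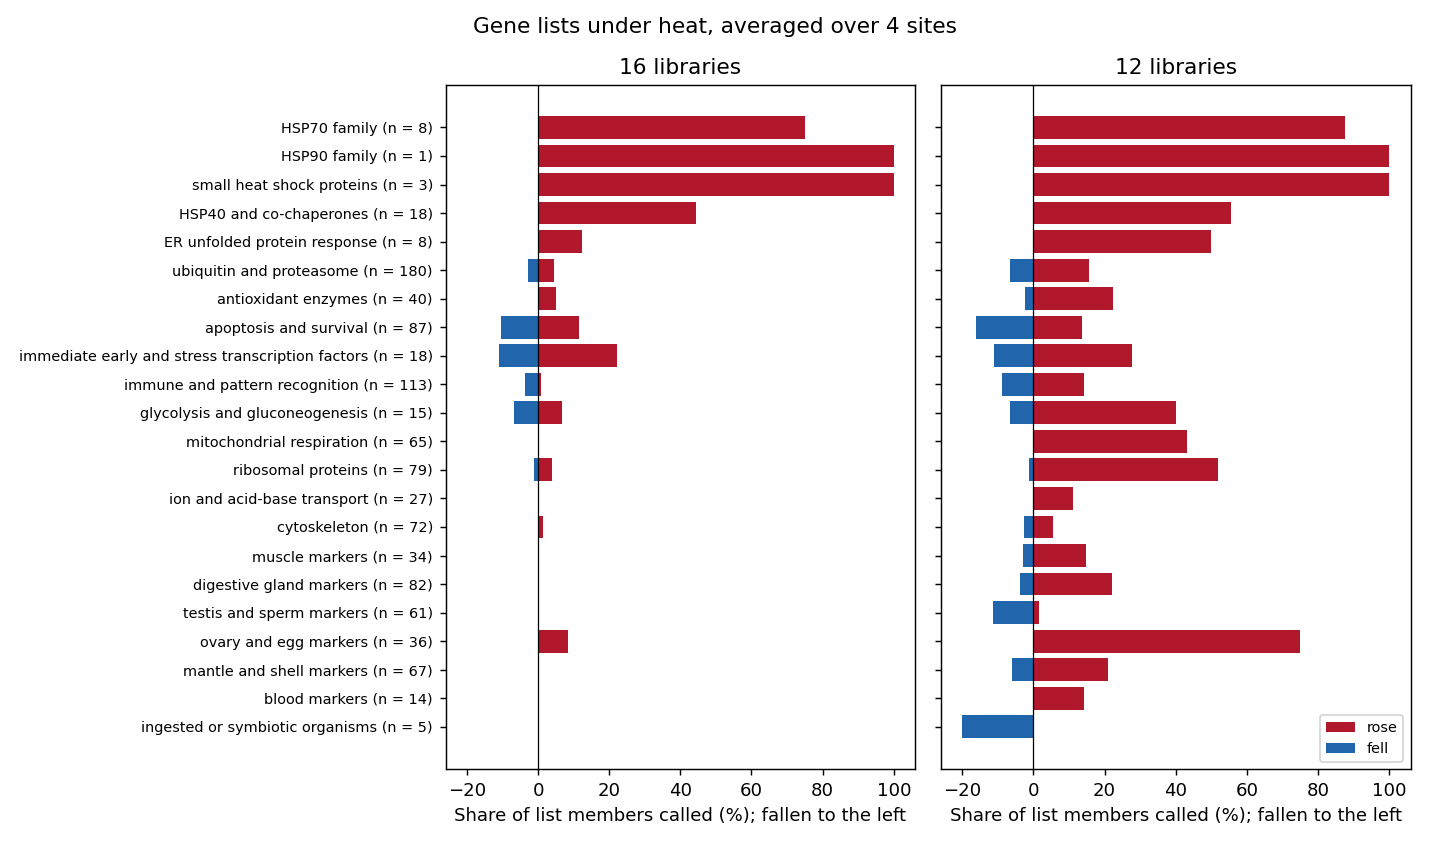
Bars give the share of each list's tested contigs (%) that rose (red, right) or fell (blue, left) under heat averaged over the 4 sites, over all 16 libraries (left) and over the 12 libraries left without the 4 that stand apart (right); the number of contigs is beside each name. The ovary and egg list goes from 3 to 27 risen contigs of 36.

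The heat effect was also taken in each region, since the design sets northern against southern sites. HSP70 contig SR_contig_18771_C3.1 rose from 203 ± 141 to 456072 ± 87098 in the north and from 536 ± 319.8 to 361842 ± 72623 in the south (SD, n = 4 each), log2 fold changes of 11.32 ± 0.42 and 9.57 ± 0.42 (SE). HSP90 contig SR_contig_806_C3.1 had 4.01 and 3.33. In the north 164 contigs rose and 106 fell, against 795 and 539 in the 12 libraries; in the south 139 rose and 111 fell, against 361 and 362 there. Both regions shared 129 risen and 67 fallen contigs, where independent lists would share 1.58 and 0.815. The regional contrasts compare different libraries but use the same estimate of each contig's spread, so their calls are not fully independent. With 1 library left out, the northern count was 174 without Slide Ranch control 1, 176 without Slide Ranch control 2 and 179 without Slide Ranch heat 1, and the southern count was 164 without Aliso Beach control 1, 162 without Aliso Beach control 2, 165 without Aliso Beach heat 2 and 517 without La Jolla heat 2. At single sites 139 contigs changed at Slide Ranch, 138 at Pigeon Point, 115 at Aliso Beach and 132 at La Jolla, against 549, 285, 403 and 205 in the 12 libraries. Of the 301 contigs risen in the averaged contrast, 300 were above 0 at every site. Their selection on the average of these same 4 effects favours that. Of all 14444 tested contigs, 5619 had the same sign at all 4 sites. The site counts were 68 without Slide Ranch control 1, 67 without Slide Ranch control 2, 73 without Slide Ranch heat 1 and 73 without Slide Ranch heat 2 at Slide Ranch, 84 without Pigeon Point control 1, 88 without Pigeon Point control 2, 76 without Pigeon Point heat 1 and 240 without Pigeon Point heat 2 at Pigeon Point, 49 without Aliso Beach control 1, 52 without Aliso Beach control 2, 55 without Aliso Beach heat 1 and 54 without Aliso Beach heat 2 at Aliso Beach, and 74 without La Jolla control 1, 82 without La Jolla heat 1 and 471 without La Jolla heat 2 at La Jolla.

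The test of the regional difference in the heat effect called no contig in limma. At an unadjusted p under 0.05 there were 197 contigs, where 722 would be expected by chance, and edgeR and DESeq2 on the recovered reads also called 0 each. Adjusted over the list alone, 2 of 8 HSP70 contigs had a smaller rise in the south, SR_contig_18771_C3.1 (log2 difference -1.75) and a binding partner of HSP70, SR_contig_16467_C3.1 (-0.95). So did the single HSP90 contig SR_contig_806_C3.1 (-0.68), whose p then has no adjustment, and no contig of the other lists passed. The fit leaves the difference of the 4 libraries in the spread, and 1112 contigs had such a p without them and 829 with a term for them. On simulated reads of the same depth and spread, limma recovered 65.0% of 200 contigs given a 4-fold regional difference and 9.50% at 2-fold. These contigs had a mean of at least 50, and the simulated libraries lacked the deviation shared by the 4. In that setting, over 16 libraries, most 2-fold differences were not detectable. No simulation was run without the 4 or with a term for them. In the 12 libraries 2 contigs were called, heat shock protein SR_contig_18769_C3.1 (log2 difference -2.44 ± 0.16 SE, adjusted p = 8.6e-04) and small heat shock protein 26 SR_contig_5896_C3.1 (-1.83 ± 0.17, adjusted p = 0.0117). La Jolla control 2 is the only La Jolla control there, with 449 and 285 normalised counts against 37.1 and 27.5 in Aliso Beach control 1. La Jolla control 1, left out there, had 109 and 198. Without La Jolla control 2 too, La Jolla has no control and drops out, and Aliso Beach alone gave differences of -0.77 and -1.08. That fit cannot separate this library from its site. As a set, 211 of the 301 risen contigs had the smaller rise in the south, with a median southern-minus-northern difference of -0.15 (log2). Among the 312 fallen contigs 150 had the smaller fall in the south, with a median of -0.029, or 0.029 in the 12 libraries. Across the 324 contigs called in either region, the slope of the southern on the northern effect was 0.937 with Pearson r = 0.976 across contigs, which are not independent replicates. Over the same contigs the slope was 0.905 without the 4 libraries and 0.960 without La Jolla heat 2. Over the contigs called in each of those fits it was 0.881 (1595 contigs) and 1.08 (607 contigs), the last on the other side of 1. Heat at La Jolla then rested on La Jolla heat 1, with 39.2% of its reads on SR_contig_83. A term for the 4 libraries cannot move these effects, as control and heat at each site hold equally many of them, so it is no check on the slope. All tested contigs gave 0.972, or 0.881 without the 4. Slopes between single sites were taken over the 613 contigs called in the averaged contrast. Aliso Beach gave 0.906 on Slide Ranch and 0.927 on Pigeon Point, and La Jolla gave 0.967 and 0.990. Within a region, Pigeon Point on Slide Ranch gave 0.977 and La Jolla on Aliso Beach 1.07. The 2 southern sites thus differed from each other about as much as the regions did.

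**Figure D4:**
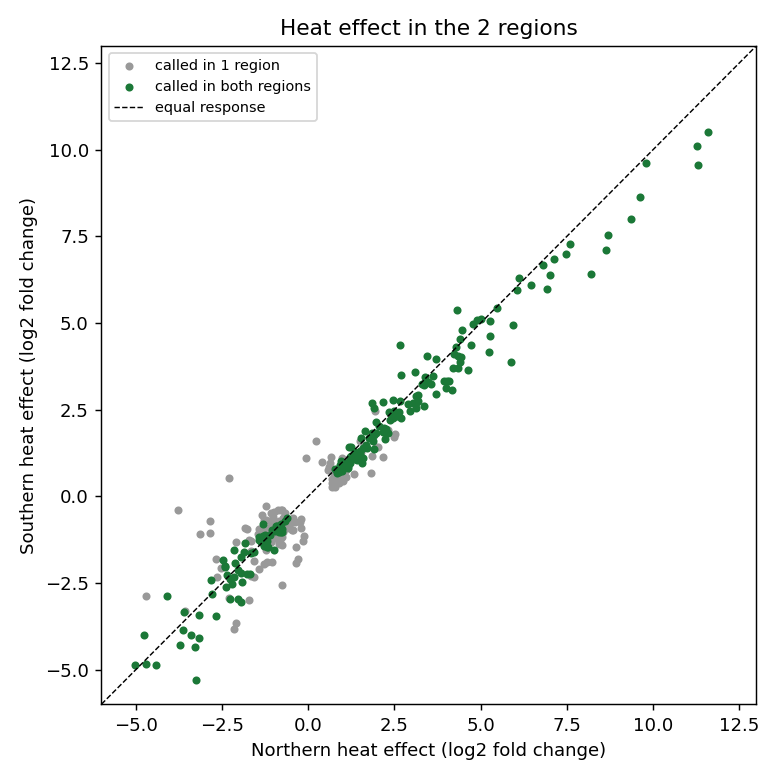
Each point is 1 of the 324 contigs called in either region, with the northern heat effect on the x axis and the southern on the y axis (log2 fold change), green where both regions called it. The dashed line marks equal effects, and the fitted slope is 0.937.

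Southern and northern controls were compared to ask which transcripts differed before heating. Vitellogenin (SR_contig_446), the egg yolk precursor, was higher in southern controls, at 43029 ± 21042 against 6480.3 ± 1602 normalised counts (SD, n = 4 each), a log2 difference of 2.60 ± 0.41 (SE). Also higher there were sialate O-acetylesterase (SR_contig_17551), by 1.65, and MCM3 (SR_contig_137240) and CDC45 (SR_contig_38225), parts of the helicase that opens DNA for replication, by 1.30 and 1.29. Lower in the south were protein cbg24793 (SR_contig_359_C3.1, -4.72), a failed axon connections homolog (SR_contig_7850_C3.1, -2.79) and leukotriene B4 12-hydroxydehydrogenase (SR_contig_5197_C3.1, -1.46). In all, 22 contigs were higher and 16 lower in southern controls, against 386 and 216 in the 12 libraries. Of 36 ovary and egg contigs 1 passed, 7 adjusted over the list alone and 16 in the 12, with a median difference of 0.55 and a camera adjusted p = 6.9e-12, or an adjusted p = 0.362 with an estimated correlation. The ribosomal protein list had a median of 0.29 (adjusted p = 1.2e-06, and adjusted p = 0.776 with an estimated correlation), and mitochondrial respiration had one of 0.27 (adjusted p = 3.1e-04, and adjusted p = 0.776 with an estimated correlation). These 3 lists are also among those that were higher in the 4 libraries that stand apart. Camera also called the glycolysis list (median 0.30, adjusted p = 0.00111) and the testis and sperm list (median 0.13, adjusted p = 0.0316) higher and the apoptosis and survival list lower (median -0.12, adjusted p = 0.023). With an estimated correlation the adjusted p of these 3 was 0.567, 0.776 and 0.394.

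Each region has only 2 sites, and some of these differences came from 1 site. Collagen alpha-6 (SR_contig_234) was called, with an averaged log2 difference of 4.42, but only Pigeon Point lay apart, at 16.1 ± 12.1 normalised counts (SD, n = 2 at each site) against 5345 ± 323 at Slide Ranch, 6273 ± 2163 at Aliso Beach and 6184 ± 2509 at La Jolla. Leukotriene B4 12-hydroxydehydrogenase had 91.7 ± 31.0 at Aliso Beach, and 386 ± 60.8 at La Jolla against 474 ± 67.5 and 565 ± 143 at the northern sites. Over the 4 pairs of a southern and a northern site, the log2 difference of vitellogenin ran from 1.89 to 3.32, of sialate O-acetylesterase from 1.44 to 1.86, of MCM3 from 0.51 to 2.08, of CDC45 from 0.68 to 1.91, of cbg24793 from -1.81 to -7.63, of the failed axon connections homolog from -2.31 to -3.28, of leukotriene B4 12-hydroxydehydrogenase from -0.30 to -2.63 and of collagen alpha-6 from 0.15 to 8.69. Of the 38 contigs called, 28 had the same sign in all 4 pairs, and 13 a difference of at least 1 in each. With site as a random effect 5 contigs were called over 16 libraries and 97 over the 12.

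No contig of the chaperone lists passed between the controls in limma over 16 libraries: among HSP70, small heat shock protein and HSP40 contigs 2, 0 and 1 had an unadjusted p under 0.05, edgeR called 0, 0 and 0, and DESeq2 1, 0 and 1. Adjusted over the list alone, 1, 0 and 1 were higher in the south. In the 12 libraries 2, 1 and 1 were higher, with a camera adjusted p = 0.00444, 0.236 and 0.0142, or an adjusted p = 0.29, 0.382 and 0.221 with an estimated correlation. Gains of a camera call in the 12 were not limited to chaperones. The endoplasmic reticulum, ubiquitin, antioxidant and cytoskeleton lists had an adjusted p = 0.913, 0.0637, 0.237 and 0.0656 over 16 libraries and 0.00973, 0.0122, 0.0103 and 0.00973 over the 12. With an estimated correlation there, the adjusted p was 0.243, 0.221, 0.221 and 0.226. The only La Jolla control among those 12 had 449 normalised counts of SR_contig_18769_C3.1, as given above. Without it the southern controls are those of Aliso Beach alone. With that library left out too, 1, 0 and 3 were higher and 1, 1 and 0 lower, with a camera adjusted p = 0.18, 0.271 and 0.0756.

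With 1 library left out, the count between the controls was 12 without Slide Ranch control 1, 10 without Slide Ranch control 2, 15 without Pigeon Point control 1, 14 without Aliso Beach control 1, 16 without Aliso Beach control 2, 23 without Aliso Beach heat 1, 23 without Aliso Beach heat 2, 18 without La Jolla control 1 and 25 without La Jolla control 2. Calls of named contigs passed the threshold no longer without some libraries, while their log2 differences kept their sign. That of vitellogenin was lost without any control library or either Aliso Beach heat library (log2 difference from 2.39 to 2.82), that of cbg24793 without Slide Ranch control 2 (-5.54 to -3.90), that of CDC45 without either Slide Ranch control library, Pigeon Point control 1, Aliso Beach control 1 or La Jolla control 1 (1.14 to 1.45) and that of leukotriene B4 12-hydroxydehydrogenase without either Slide Ranch control library, Pigeon Point control 1, Aliso Beach control 1 or La Jolla control 2 (-1.64 to -1.29). The call of the failed axon connections homolog was lost without either Slide Ranch control library, Pigeon Point control 1, either Aliso Beach control library or either La Jolla control library (-3.06 to -2.53). The call of sialate O-acetylesterase was lost without any library except Pigeon Point heat 1, Pigeon Point heat 2, La Jolla heat 1 and La Jolla heat 2 (1.51 to 1.79), and that of MCM3 without any library except Pigeon Point control 2, and in edgeR (1.05 to 1.55 without 1 library).

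Vitellogenin also stood higher in the south under heat, at 39985 ± 24821 against 8289 ± 2910.2 normalised counts (SD, n = 4 each), a log2 difference of 2.01 ± 0.41 (SE). It stood at 59826 ± 3672 at Aliso Beach (SD, n = 2) and at 31548 in La Jolla heat 2. La Jolla heat 1, 1 of the 4 libraries that stand apart, had 8739.9, within the northern range of 4209 to 11078. Over the 4 pairs of a southern and a northern site the difference of vitellogenin ran from 0.89 to 3.13. Of the 36 ovary and egg contigs 3 were higher (5 adjusted over the list alone and 6 in the 12 libraries), with a camera adjusted p = 2.8e-06, or an adjusted p = 0.496 with an estimated correlation. In all, 110 contigs were higher and 58 lower in southern than in northern animals, against 778 and 576 in the 12 libraries. Of these 168 calls, 151 had the same sign in all 4 pairs of a southern and a northern site, and 32 a difference of at least 1 in each. Of the contigs that differed between controls, 20 of 22 higher and 14 of 16 lower ones also differed the same way under heat, where independent lists would share 0.168 and 0.0642. The apoptosis and survival list lay lower in the south, as it did in controls, with a median of -0.34 and a camera adjusted p = 2.2e-05, or an adjusted p = 0.109 with an estimated correlation, although none of its 87 members passed alone in limma (22 at an unadjusted p under 0.05, 1 called by edgeR and 9 by DESeq2). Adjusted over the list alone, 7 were lower and 1 higher, and in the 12 libraries 16 and 1. The ribosomal, mitochondrial respiration and glycolysis lists lay higher (camera adjusted p = 2.4e-05, 6.2e-05 and 0.0361), which was lost with an estimated correlation (adjusted p = 0.652, 0.663 and 0.652). With 1 library left out, the count of all contigs was 60 without Slide Ranch control 1, 60 without Slide Ranch control 2, 24 without Slide Ranch heat 1, 25 without Slide Ranch heat 2, 38 without Pigeon Point heat 1, 45 without Aliso Beach control 1, 45 without Aliso Beach control 2, 25 without Aliso Beach heat 1, 23 without Aliso Beach heat 2, 58 without La Jolla heat 1 and 351 without La Jolla heat 2. With site as a random effect it was 22 over 16 libraries and 1313 over the 12.

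Within a region, 20 contigs differed between the northern control groups and 20 between the southern ones in limma, against 86 and 69 in the 12 libraries. With 1 library left out, the northern count was 12 without Slide Ranch control 1 and 8 without Slide Ranch control 2, and the southern count was 12 without Slide Ranch control 1, 12 without Slide Ranch control 2, 11 without Slide Ranch heat 1, 11 without Slide Ranch heat 2, 6 without Aliso Beach control 1, 8 without Aliso Beach control 2 and 8 without La Jolla control 1. No contig differed in its heat effect between the 2 sites of a region in limma over 16 libraries, and 0 northern and 2 southern contigs did in the 12. Over 16 libraries 151 northern and 174 southern contigs had an unadjusted p under 0.05, edgeR called 0 and 0, and DESeq2 called 2 and 3. At an unadjusted p under 0.05 there were 873 and 648 in the 12 libraries, and 899 and 853 with a term for the 4. Without Pigeon Point heat 2, limma called 2 northern contigs.

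The last comparison asked whether contigs that rose in the north and rose less in the south started higher in southern controls. It used different control libraries for the response and for the baseline, because the same control on both sides links them. With the response from controls numbered 1 and the baseline from controls numbered 2, 52 such contigs had a median southern-minus-northern baseline of 0.14 (log2), against a median of 0.065 for 10000 random sets matched on mean level (permutation p = 0.166, two-sided, and 0.234 adjusted over the settings run). The other way round, 73 contigs had a median of -0.13 (permutation p = 4.0e-04, adjusted 0.0016), in the opposite direction. The sign of the median thus changed with the control libraries used. This split by number was not neutral. Controls numbered 1 include Pigeon Point control 1 and La Jolla control 1, which stand apart, while no control numbered 2 does. The change of sign therefore cannot be told apart from the deviation of those libraries. Within Slide Ranch and Aliso Beach, which hold no such library, disjoint controls gave a median of 0 each way. A median of exactly 0 may come from contigs without reads in either baseline library, which was not examined. Over the 12 settings run, 5 of them planned, the median lay above 0 in 8 and below 0 in 2. In each of the 12 it lay above the median of the other contigs that rose in the north. With disjoint controls split by number, the medians of those others were -0.10 (25 contigs) and -0.29 (12 contigs). The settings share libraries, and this difference was not tested. The permutations draw contigs and not animals, and contigs are not independent replicates.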

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

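The tests of the tissue lists, of gene lists in the regional difference and of other splits of the libraries were set before their results were seen, and the other tests here were chosen after.

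Across 6 library measures, each taken in the 4 sets of 1 region and treatment, 10 of 24 tests found a library far from the other 3 of its set, where chance gives about 1 in 20. The share of reads on contig SR_contig_83 was 17.3% in Pigeon Point heat 1, 17.1% in La Jolla control 1 and 39.2% in La Jolla heat 1. Slide Ranch heat 1 had 23.4 M reads, against 19.8 to 20.3 M in the other 3. Contigs at 0 numbered 703 in Pigeon Point heat 1 and 453 in La Jolla control 1. La Jolla heat 1 had the most, 830, against 270 to 380 in the other 3 of its set, which fell short of the test's mark. The 100 most abundant contigs took 48.7% in Pigeon Point control 1, 53.7% in Pigeon Point heat 1, 49.3% in La Jolla control 1 and 65.7% in La Jolla heat 1. All but the Slide Ranch value belong to the 4 libraries that stand apart.

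In these 4 libraries 8060 contigs differed. Reads lost to contig SR_contig_83 are argued against as the whole cause. Its share of reads alone would shift all other contigs by -0.339 (log2). Their common shift was -0.93 (log2 CPM, quartiles -1.52 and -0.34, median SE 0.217). Of the 14443 others, 51.5% departed from that common shift. This percentage decides little, as the 4 were grouped on values whose scaling already removes a common factor, so it nearly restates the grouping. A batch of preparation or sequencing shared by the 4 stays open, as the labels name none. Of the contigs that differed between the Pigeon Point numbers, 97.0% had the same sign at La Jolla, against 61.7% at Slide Ranch and 44.2% at Aliso Beach, but this restates the likeness by which the 4 were grouped, and any state shared by their animals would give it too. Another mix of tissues stays open: 55.6% of the 14145 contigs outside the tissue lists differed and 55.8% of all 14444, but so few contigs are in those lists that the share could hardly move.

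The southern heat effect lay below the northern in 5 lists by camera on the difference itself: HSP70 (adjusted p = 7.1e-04), apoptosis and survival (0.00697), immune recognition (0.0392), muscle (7.1e-04) and mantle and shell (0.0264). With an estimated correlation none passed (adjusted p from 0.527 to 0.673). In the 12 libraries camera called 11 lists below, these 5 and small heat shock proteins (adjusted p = 2.7e-04), endoplasmic reticulum (0.00315), HSP40 and co-chaperones (0.0373), antioxidants (0.0285), digestive gland (0.00929) and ovary and egg (0.00499). With an estimated correlation none of the 21 lists passed there (smallest adjusted p = 0.276). List medians lay below 0 in 19 of 21 lists over 16 libraries and 20 of 21 in the 12, so the direction was not particular to the lists called. Without the 4 libraries the difference was -2.44 (log2) for SR_contig_18769_C3.1 and -1.83 for SR_contig_5896_C3.1. With La Jolla control 2 also left out, La Jolla drops out for want of a control, and the differences were -0.77 and -1.08.

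The smaller southern rise of the risen contigs (median -0.15) was not removed with the 4 libraries, where it was -0.17. Over the 324 contigs called in either region the slope of southern on northern effects was 0.937, with 0.905 without the 4 and 0.960 without La Jolla heat 2; it turned to 1.08 only over the 607 contigs called in that last fit, and the 312 fallen contigs had a median difference of -0.029. Chance could not be excluded, as 10 of 100 splits, the real one included, gave a median as large, up to 0.227. These splits ignored site and could hold the 4 libraries unevenly, which the real split does not. Their share is thus only a rough measure of chance. The other 2 pairings of the sites gave at most 0.0702, but 3 pairings are too few for a share under 0.05. Between the 2 southern sites the slope of La Jolla on Aliso Beach, 1.07, lay about as far from 1 as that between regions. A higher southern level before heating stays undecided, at 0.14 and -0.13 with disjoint controls, and a regional difference in the response stays open.

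For the difference between southern and northern controls, a poorer match of southern reads to a reference possibly made from northern animals stays open: it would lower southern values, and 42.1% of the 38 contigs called over 16 libraries and 35.9% of the 602 called in the 12 were lower, but the scaling of each library removes a general lowering. A different share of egg-bearing animals cannot be told apart from region: with the ovary and egg score in the model, 33 of 38 calls remained over 16 libraries but 0 of 602 over 12. The score was higher in each of the 4 libraries than in the other library of its group, such as 1.07 against 0.32 in La Jolla heat, and the first fit called 3023 contigs. Among the controls of the 12, southern scores lay from -0.25 to 0.26 and northern ones from -1.35 to -0.51. Why the calls moved was not tested. The testis and sperm list also lay higher in southern controls (median 0.13, camera adjusted p = 0.0316, or adjusted p = 0.776 with an estimated correlation). Regional biology stays open and untested.

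Other splits of the libraries were fitted with site in the model for heat, and without it between regions and for the regional difference in the heat effect. A heat split that falls along the sites leaves no room for a site term and was fitted without it. For heat over the 4 sites, 2 of 100 splits, the real one included, gave at least the real 900 contigs. The other gave 3419 and put all 4 libraries that stand apart on the same side, a structure of the samples. Few splits thus reached the heat count, but it was not the highest. Without those libraries 2712 contigs were called for heat. In the north and south 1 and 1 of 35 splits reached the real 237 and 192, with at most 65 and 35 in the others. Those highest counts came from splits between the 2 sites of a region, fitted without site, so they count site differences. Over the 8 controls alone, 1 of 35 splits reached the real 3, against at most 1. Over the 8 heated libraries alone the real split called 0 contigs, so all 35 of 35 splits gave as many (at most 1), and for the regional difference in the heat effect it called 0, as did all 100 of 100 (at most 0). With a real count of 0 every split reaches it, so these 2 counts say nothing about chance.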

How the results depend on the processing

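The settings with the 4 libraries removed or modelled, and some baseline settings, were chosen after the data were examined. Pseudocounts, no filter, TMM, robust shrinkage and edgeR kept every count of calls within 1.5 times; a mean of at least 50 gave 11 contigs between southern control sites, from fewer contigs tested, and a log2 change of at least 1 left 327 heat calls by its construction. For the following settings the cause was not tested. DESeq2 called 1313, 579, 509, 340, 792 for heat over the 4 sites, north, south, controls and heated animals between regions, 257, 279, 218, 296 at Slide Ranch, Pigeon Point, Aliso Beach and La Jolla, and 115 and 75 between northern and southern control sites, and 2 and 3 for the site responses. Without the 4 libraries the calls were 2712, 1334, 723, 602, 1354 for heat over the 4 sites, north, south, controls and heated animals between regions, 549, 285, 403, 205 at Slide Ranch, Pigeon Point, Aliso Beach and La Jolla, and 86 and 69 between northern and southern control sites, 2 for the interaction and 2 for the southern site response. With a term for them they were 3531, 1472, 1288, 785, 2019 for heat over the 4 sites, north, south, controls and heated animals between regions, 330, 920, 271, 775 at Slide Ranch, Pigeon Point, Aliso Beach and La Jolla, and 89 and 82 between northern and southern control sites. edgeR with that term gave 3481, 1398, 1168, 831, 1896 for heat over the 4 sites, north, south, controls and heated animals between regions, 348, 734, 282, 613 at Slide Ranch, Pigeon Point, Aliso Beach and La Jolla, and 91 and 85 between northern and southern control sites. Only the libraries compared (fewer samples) gave 166, 147, 8, 9 for north, south, controls and heated animals, 328, 12, 300, 20 at the 4 sites and 0 and 3 between control sites. Site as a random effect gave 5, 22 between regions for controls and heated animals, and 97, 1313 without the 4 libraries. Leaving out Slide Ranch, Pigeon Point, Aliso Beach or La Jolla (fewer samples) gave 86, 154, 83 and 118 in its region. Leaving out 1 library gave 403 to 1097, 174 to 343, 162 to 517, 10 to 51, 23 to 351 for the first 5 results, 67 to 151, 76 to 240, 49 to 122, 74 to 471 at the sites, 8 to 26 and 6 to 27 between control sites and 0 to 2 for the northern site response; the regional slope ran from 0.869 to 1.08 over the contigs called in each fit, and over the contigs called with all 16 libraries it was 0.960 without La Jolla heat 2.

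Same-numbered libraries deviated together at Pigeon Point and La Jolla (correlation of deviations 0.69 and 0.64), where the libraries numbered 1 are those that stand apart, but not at Slide Ranch (-0.059, and 0.10 at Aliso Beach), so the numbers were not taken to pair the libraries. A replicate block gave 3093, 1119, 879 calls for heat over the 4 sites, north and south, 251, 536, 214, 457 at the sites and 1 for the southern site response. With an estimated correlation these lists lost their call: ER unfolded protein response (adjusted p = 0.478), antioxidant enzymes (adjusted p = 0.478), immediate early and stress transcription factors (adjusted p = 0.0714), mitochondrial respiration (adjusted p = 0.483), ribosomal proteins (adjusted p = 0.478), digestive gland markers (adjusted p = 0.478), testis and sperm markers (adjusted p = 0.593), ovary and egg markers (adjusted p = 0.136). Without the 4 libraries these gained one under heat: glycolysis and gluconeogenesis (0.0085, and adjusted p = 0.146 with an estimated correlation), ion and acid-base transport (0.0418, and adjusted p = 0.145 with an estimated correlation), mantle and shell markers (0.00699, and adjusted p = 0.14 with an estimated correlation). Of the 78 values of named contigs that were called, 21 lost their call in at least 1 alternative. Signs turned in 3 cases, none of them called: 0.0258 without Slide Ranch heat 2, 0.0162 without Pigeon Point control 2, 0.0475 without La Jolla heat 1 (1 riboflavin biosynthesis contig, -0.22 to 0.026 without 1 library, and 1 short-chain dehydrogenase contig, -0.18 to 0.048).

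All 12 settings of the baseline comparison are given, since they disagree in sign. The p-values are adjusted over the 12, and 5 passed, 3 above 0 and 2 below. The 5 planned settings gave 0.140 (adjusted p = 0.234), -0.134 (adjusted p = 0.0016), 0.0587 (adjusted p = 0.253), 0.0456 (adjusted p = 0.155), 0.0695 (adjusted p = 0.0336): disjoint controls both ways, shared controls, and the 500 largest rises both ways. Of the 7 added, shared controls without the 4 libraries gave 0.26 (6.0e-04). Taking response and baseline from different sites gave 0.094 (0.234), -0.0279 (0.0382) and 0.12 (0.208). Within Slide Ranch and Aliso Beach, shared controls gave 0.13 (6.0e-04) and disjoint controls 0 (0.659) and 0 (0.253).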

Other observations

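Other named contigs changed far outside the chaperone lists under heat. An apoptosis regulator R1-like contig (SR_contig_13490) rose from 9892 ± 1530.1 to 79701 ± 8638 normalised counts (SD, n = 8 each), a log2 fold change of 3.02 ± 0.12 (SE). MEGF6, a protein with repeated EGF-like domains (SR_contig_18931), fell by 2.34 on the log2 scale, and CEP164 (SR_contig_10590), a centriole protein needed for cilia, by 2.20. The mean standardised level of the ovary and egg list ran from -1.35 in Pigeon Point control 2 to 1.07 in La Jolla heat 1.

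The test in this paragraph was chosen after the result was seen, as 1 of 12 settings. Within Slide Ranch and Aliso Beach, contigs with the smaller southern rise seemed to start higher in the south when the same controls served both sides (median 0.13, 300 contigs). With disjoint controls the median was 0 each way, over 158 and 151 contigs. Shared control libraries may produce the apparent higher baseline there, but the change in the contigs compared cannot be told apart from this. Simulated reads of all 16 libraries, with equal baselines and equal responses, gave a median of 0.20 for shared controls and 0.0378 and 0.0303 for disjoint ones. Slide Ranch and Aliso Beach alone were not simulated. Over all 16 libraries the shared-control median (0.059) lay between the disjoint ones, so the hypothesis was not borne out there.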
